A study of Homo sapiens with 2 samples.

How the data were processed

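RNA from 2 cultures of the PLC/PRF/5 line under hypoxia was sequenced, 1 with an empty vector and 1 with NFX1 overexpression. Each sample's group was taken from its genotype label. Per the submitters' processing notes, TopHat2 2.1.0, Cufflinks 2.2.1 and the hg19 genome were used; settings, annotation and library type were not given in the sources used here. The deposited table has, per the file headers, FPKM for each library. Per the file headers the authors also gave a log2 fold change, a test statistic (a score), and a p-value and q-value per row. The sources used here do not state how the authors scaled the libraries. FPKM depends on an assumed transcript length and is inflated for loci about as short as a sequenced fragment.

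Of 28658 rows, 1651 without a symbol and 492 with several symbols stayed out of the gene comparisons. For the 491 symbols with more than 1 row, the row with the highest mean was used. The change of a gene was log2((NFX1 FPKM + 1)/(vector FPKM + 1)), over 11182 genes with FPKM of at least 1 in at least 1 library. With 1 library per group no p-value was computed. Starts of loci were converted to count from 1.

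Before the data were examined, 32 gene lists, the 2-fold limit and the rule for named genes were fixed. The rule always named 7 genes (NFX1, LGALS9, HIF1A, CARNS1, CNDP2, TFEB and CD274), the 12 greatest increases and 12 greatest decreases among genes with FPKM of at least 5 in a library (without small RNA genes), and up to 4 members of each list by size of change. Other members named as examples, and the neighbours of NFX1, were chosen after their values were seen. A few genes that the rule selects are not reported here, though they stayed in the counts and list medians. A list's median was set against 10000 random lists drawn from the same 20 expression bins, for lists with at least 3 measured genes. The percentile describes these libraries and is not a p-value, and some genes belong to several lists.

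Depth was estimated because the table has no counts. Among 2226 low rows, 59.3% had ratios within 0.02 (log2) of ratios of whole fragments, against a median of 8.63% for shifted steps, which put 1 fragment in the NFX1 library at 0.870 times its worth in the vector library. Fragments per gene were then estimated with GENCODE transcript lengths, matched by symbol and used without coordinates because that annotation is on another build. Exact (Clopper-Pearson) 95% intervals of a fold from these estimates cover counting error only. Their width depends on the length used, the median over a gene's transcripts, and a length that is too short makes an interval too wide.

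The trend of the change on GC content, log2 transcript length and expression was fitted with cubic splines on genes within 2-fold and subtracted, for 10996 genes (98.3%) with a GENCODE transcript. This adjustment was chosen after list medians had been seen, and 1 form of it was fitted. The limits for unnamed loci were also chosen after some values had been seen; a minimum length of 400 bp was tried for them and not kept, because it would have left 2 of 17. The bounds of the tests on glycolytic and cell division genes were rewritten after their values were seen, from a difference between lists to the opposite side of the random lists both as deposited and after adjustment.

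The steps were tested on simulated libraries with the real genes' mean values, which carry counting error only and no spread between cultures. Changes were planted only in genes with a mean FPKM of at least 5, so the shares found say nothing about lower genes. Of genes changed 3-fold up, 100% of 50 passed the 2-fold limit, and of genes changed 3-fold down, 98.0% of 50. Of genes changed 1.5-fold in either direction, 0% of 50 did. A list shifted by -0.20 in the presence of a GC trend was recovered at -0.20 after adjustment, and 2 of the other 29 lists were set apart then, against 8 before adjustment. That planted trend was linear in the same GC values that the adjustment used, so it does not show how fully the real trend is removed. Alternatives covered the pseudocount (0.1 and 5), the filter, 3 scalings, summed rows, row status, the fold limits of 1.5 and 4, and 10 bins. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.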

Results

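RNA was measured by sequencing in PLC/PRF/5, an established human hepatocellular carcinoma cell line, cultured under hypoxia. 1 library came from cells carrying an empty vector and 1 library from cells overexpressing NFX1, a zinc-finger transcription factor. With 1 library per group there was no replicate check and no test across samples, so every difference below compares these 2 libraries and not the conditions. The table lists FPKM for 28658 rows, of which 24991 distinct single-gene symbols were used. FPKM of at least 1 in at least 1 library was found for 11182 genes. The smallest steps between low values placed the NFX1 library at 1.15 times the depth of the vector library, and olfactory receptor genes gave about 26.3 M fragments for the vector library and 29.9 M for the NFX1 library. Changes are log2 ratios of FPKM + 1, NFX1 over vector, which understate the change of genes with low values.

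The comparison asked what NFX1 overexpression changes in hypoxic tumour cells, in a study of carnosine, intracellular pH and lysosome-dependent immune evasion. NFX1 itself (chromosome 9, 33290418 to 33371155, hg19) had 4.21 FPKM in the vector library and 56.0 FPKM in the NFX1 library, 13.3 times as much, with a 95% exact counting interval of 11.96 to 14.51 for the fold. Its change of 3.45 was the greatest among genes with FPKM of at least 5 in a library. The 10 expressed genes within 500000 bp of NFX1 had a median change of -0.04, from -0.42 for SUGT1P1 to 0.46 for AQP3, a water and glycerol channel. LGALS9, which encodes the immune checkpoint ligand galectin-9, had 0.138 FPKM in the vector library and 0.0180 FPKM in the NFX1 library. With the transcript length of 754 bp used here, those values correspond to an estimated 3 and 0 fragments. The NFX1 value is above 0, so the estimate of 0 is a rounded one and both estimates may be too low. The value in the NFX1 library was the lower one, but both lie near the floor. Whether LGALS9 differed cannot be told from so few fragments.

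**Figure D1:**
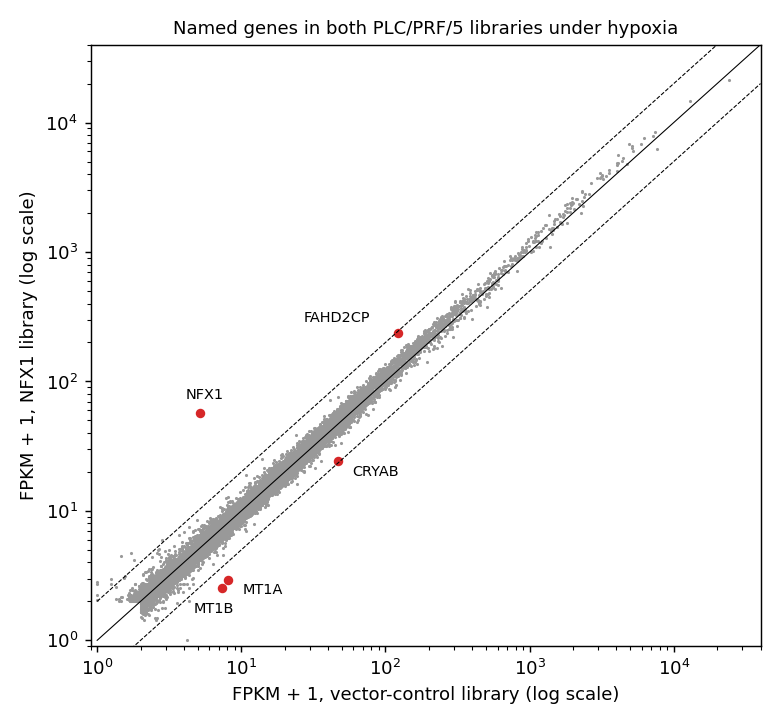
FPKM + 1 of each named gene with FPKM of at least 1 in a library, vector library on the x axis and NFX1 library on the y axis, both on log scales. The solid line marks equality and the dashed lines a 2-fold difference of FPKM + 1. NFX1 lies far above the line, at 4.21 and 56.0 FPKM.

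Few other genes differed by much. At least 2-fold higher values were found for 12 genes and at least 2-fold lower values for 4 genes, and 99.4% of the 11182 genes lay within 1.5-fold. After removal of the trend with base composition, described further on, the numbers were 7 higher and 5 lower. These cover the 10996 genes with a GENCODE transcript, which some of the 12 lacked. Of the 16 genes as deposited, 13 had FPKM under 5 in both libraries, and the other 3 were NFX1 and the metallothionein genes MT1A and MT1B. MT1A was 7.11 FPKM in the vector library and 1.93 FPKM in the NFX1 library, and MT1B was 6.36 and 1.55 FPKM. Both are near-identical to MT1X, which had 7634 FPKM in the vector library, so their values are uncertain. Counting error alone gave 3 genes beyond 2-fold among 10762 simulated unchanged genes.

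Among genes with FPKM of at least 5 in a library, the greatest increases from the vector to the NFX1 library, next to NFX1 itself, were in the pseudogene FAHD2CP (120 to 236 FPKM), HCST, an adaptor of natural killer receptors (2.70 to 5.52 FPKM), CATIP-AS1 (9.79 to 17.8 FPKM) and the small nucleolar RNA host gene SNHG9 (40.6 to 71.3 FPKM). NOXA1, an activator of NADPH oxidase, had a change of 0.79. NUPR1, a stress-induced nuclear protein, went from 46.1 to 75.1 FPKM, and ENHO, which encodes adropin, from 22.9 to 37.6 FPKM. The histone gene HIST1H2AH (3.95 to 7.45 FPKM), PRODH2 (6.80 to 11.5 FPKM) and the tight-junction gene CLDN4 (7.14 to 11.9 FPKM) were also among the 12 highest. Other than for NFX1, these changes were smaller after removal of the trend with base composition. That of FAHD2CP went from 0.97 to 0.73, that of NOXA1 to 0.60 and that of ENHO from 0.69 to 0.46.

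At the other end, CRYAB, a small heat shock protein, had 45.5 FPKM in the vector library and 23.2 FPKM in the NFX1 library, with a 95% counting interval of 0.456 to 0.559 for the fold. The protease inhibitor SLPI had 6.45 and 3.54 FPKM, ISM2 11.3 and 6.91 FPKM, and HAL, which degrades histidine, 9.86 and 6.04 FPKM. ORM1, an acute-phase protein of hepatocytes, had 31.4 and 20.6 FPKM, and C19orf81 23.4 and 15.2 FPKM. The histone genes HIST1H4H (5.41 and 2.91 FPKM), HIST1H4I (5.82 and 3.56 FPKM) and HIST1H2BG (6.49 and 4.15 FPKM) were also among the 12 lowest.

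The changes followed base composition. In the fifth of genes with the lowest transcript GC content (median 40.3%) the median change was -0.11, and in the fifth with the highest (median 62.7%) it was 0.20. GC content, transcript length and expression level together took 40.5% of the variance across genes, and GC content alone 37.5%. The lists below are therefore set against random lists as deposited and after removal of this trend, an adjustment chosen after the data had been seen. A list was set apart when its median lay in the lowest or the highest 2.5% of the medians of 10000 random lists matched on expression. As deposited, 9 of the 30 lists with enough measured genes stood apart, 2 higher and 7 lower. In simulated libraries with no change and no trend, counting error alone set 3 of 30 lists apart. After removal of the trend 6 of those 9 stayed apart on the same side. Over all 30 lists, 5 then stood apart on the high side and 9 on the low side, more than as deposited.

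Targets of hypoxia-inducible factors other than glycolytic genes were lower in the NFX1 library. The median change of 34 measured members was -0.18, below all 10000 random lists (percentile 0), with 26 members lower and 8 higher. LOX, which crosslinks collagen, had 3.21 FPKM in the vector library and 1.74 FPKM in the NFX1 library, the caveolar protein CAV1 47.9 and 32.7 FPKM, and PLOD2, a lysyl hydroxylase, 74.3 and 54.3 FPKM. After removal of the trend the median was -0.21 and 31 of the 34 members were lower. HIF1A, which encodes the oxygen-regulated subunit, had 15.3 and 13.2 FPKM, a fold of 0.861 with a counting interval of 0.794 to 0.915; its log2 change was -0.20 as deposited and -0.11 after removal of the trend.

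**Figure D2:**
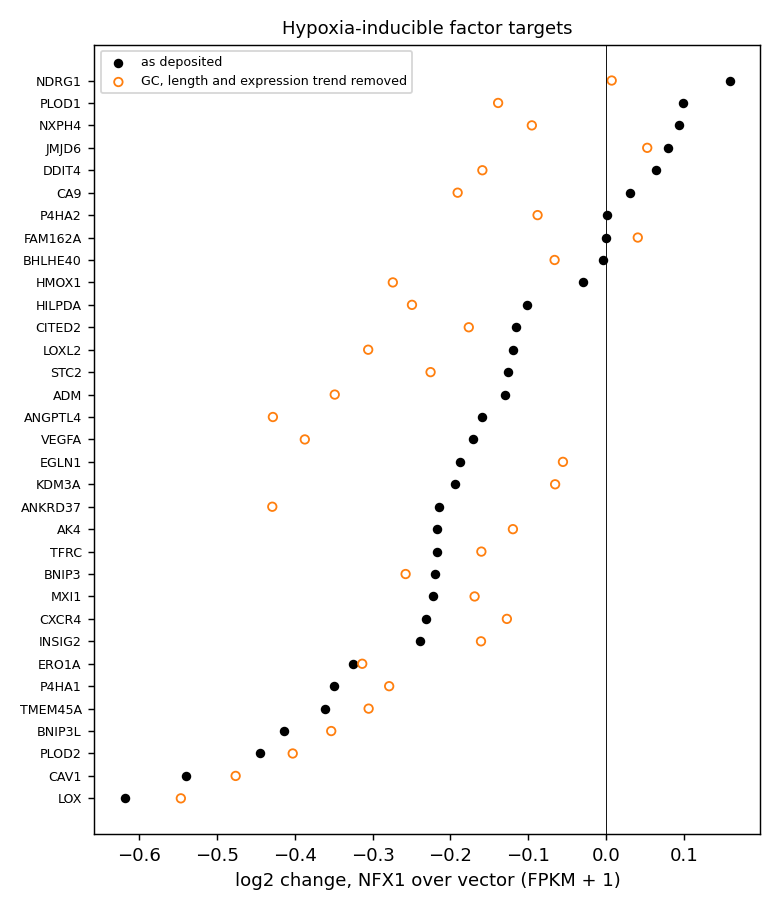
log2 change, NFX1 over vector, of 33 measured targets of hypoxia-inducible factors. Filled points are the values as deposited and open points those after removal of the GC, length and expression trend, after which 30 of the 33 lie below 0.

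Glycolytic genes did not stand apart, at a median of 0.10 over 23 genes and percentile 33.3 with 18 genes higher, nor after removal of the trend, at a median of -0.04 and percentile 9.13 with 16 genes lower. Of the 23, LDHA, lactate dehydrogenase A, had 1374 and 1085 FPKM and the aldolase ALDOC 4.23 and 6.13 FPKM. Genes of carnosine and histidine-dipeptide metabolism had a median of 0.02 over 8 genes (percentile 74.2, and 32.8 after removal of the trend). Carnosine dipeptidase CNDP2 had 26.3 and 29.4 FPKM, a change of 0.16 as deposited and 0.08 after removal of the trend. The counting interval for its fold was 0.968 to 1.26, from fragments estimated with a transcript length of 578 bp. A longer transcript would narrow that interval. The peptide transporter SLC15A1 had a change of 0.26. Carnosine synthase CARNS1 had 0.194 and 0.123 FPKM, with a counting interval of 0.311 to 1.34. Plasma membrane pH regulators had a median of 0.03 over 11 genes (percentile 33.8) with 8 genes higher, and lay at percentile 5.35 with 8 genes lower after removal of the trend. The anion exchanger SLC4A2 had 137 and 167 FPKM, a change of 0.28 that was 0.02 after removal of the trend, and the carbonic anhydrase CA9 had 132 and 135 FPKM, a change of 0.03 that was -0.19 afterwards, while CA2 had a change of -0.26 and CA12, at 1.17 FPKM in the vector library, -0.40.

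Lysosomal gene groups stayed within the random lists. Subunits of the vacuolar proton ATPase, which acidifies lysosomes, had a median of 0.00 over 19 genes (percentile 7.21), with ATP6V0E2 at 0.36 and ATP6V0B at 0.35, which were 0.16 and 0.12 after removal of the trend. Lysosomal hydrolases had a median of 0.06 over 40 genes (percentile 25.3), with NAGLU at 0.34 (0.13 afterwards) and ARSB at -0.31 (-0.30 afterwards). Lysosomal membrane and trafficking proteins had a median of 0.06 over 42 genes (percentile 56.0), with the proton channel TMEM175 at 0.42 (0.24 afterwards). TFEB, a regulator of lysosomal genes, had 2.19 and 3.14 FPKM, a fold of 1.43 with a counting interval of 1.06 to 1.91 that does not cover the trend; its log2 change was 0.37 as deposited and 0.20 after removal of the trend. Autophagy genes had a median of -0.03 over 35 genes (percentile 11.4), with ATG4D at 0.31 (0.12 afterwards) and WIPI1 at -0.26 (-0.24 afterwards). Removal of the trend set none of these 4 lists apart.

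For genes of immune recognition, the MHC class II list stood apart, with a median of 0.32 over 6 genes (percentile 99.9, and 99.99 after removal of the trend), but none of the 6 encodes a classical class II chain. HLA-DRA was listed at 0 in both libraries, and CD74, the invariant chain, had 0.0530 and 0.0231 FPKM. Of the 6, HLA-DMB, which loads peptides onto class II molecules, had 15.5 and 22.3 FPKM, HLA-DMA 1.35 and 2.22 FPKM, and the transcription factor subunits RFXANK and RFXAP had changes of 0.39 and 0.26, which were 0.16 and 0.38 after removal of the trend. Lower values were found for RFX5, at -0.11, and the protease CTSS, at -0.15. With no filter on low values the percentile of this list was 58.2. MHC class I genes (median 0.07 over 20 genes, percentile 41.8, and 6.43 after removal of the trend), with PSMB9 at 0.52, and immune checkpoint ligands (median -0.02 over 15 genes, percentile 16.5, and 33.1 afterwards), with TNFSF9 at 0.41 (0.26 afterwards), did not stand apart. CD274, which encodes PD-L1, had 0.00890 and 0.0836 FPKM, an estimated 1 and 9 fragments, with a counting interval of 1.09 to 343 for the fold. Galectins had a median of 0.06 over 6 genes (percentile 62.4), with LGALS3 at 107 and 85.4 FPKM and LGALS2 at 1.61 and 3.74 FPKM, and after removal of the trend the median turned to -0.12 (percentile 2.27). Reported targets and partners of NFX1, NFX1 included, had a median of 0.03 over 11 genes (percentile 48.9, and 81.0 after removal of the trend), with TERT, the catalytic subunit of telomerase, at 2.56 and 3.09 FPKM, a change of 0.20 that was 0.04 after removal of the trend.

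The listed replication-dependent histone genes were lower in the NFX1 library, with a median of -0.26 over 16 genes, below all 10000 random lists, with 13 members lower and 3 higher. Of the histone genes outside this list that are named above, HIST1H2AH had a change of 0.77 and HIST1H4I of -0.58. The linker histone HIST1H1C had 296 and 220 FPKM and HIST1H4C had a change of -0.54. Cell division genes had a median of 0.03 over 38 genes (percentile 32.8) as deposited and lay at percentile 99.9 after removal of the trend, with PLK1 at 60.2 and 82.0 FPKM and MYBL2 at 127 and 174 FPKM, changes of 0.44 and 0.44 that were 0.34 and 0.24 after removal of the trend. Metallothioneins had a median of -0.24 over 6 genes (percentile 0.050), and without the uncertain MT1A and MT1B -0.12 over 4 genes (percentile 2.27), with MT2A at 24314 and 21225 FPKM and MT1X at 7634 and 6301 FPKM. After removal of the trend the median over the 6 genes was -0.43, with all 6 lower. Genes of the unfolded protein response had a median of -0.03 over 28 genes (percentile 0.090), with 15 lower and 13 higher, and -0.13 with 22 lower after removal of the trend. The chaperone DNAJB9 had 26.4 and 19.0 FPKM, SEL1L 12.3 and 9.79 FPKM, and TRIB3, in the other direction, 31.2 and 38.8 FPKM, a change of 0.31 that was 0.10 after removal of the trend. Cytosolic ribosomal protein genes had a median of 0.21 over 74 genes and 73 of them were higher, but their percentile among similarly abundant genes was 97.1 as deposited. After removal of the trend the median was smaller, at 0.11 with 67 genes higher, and the percentile was 100.

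**Figure D3:**
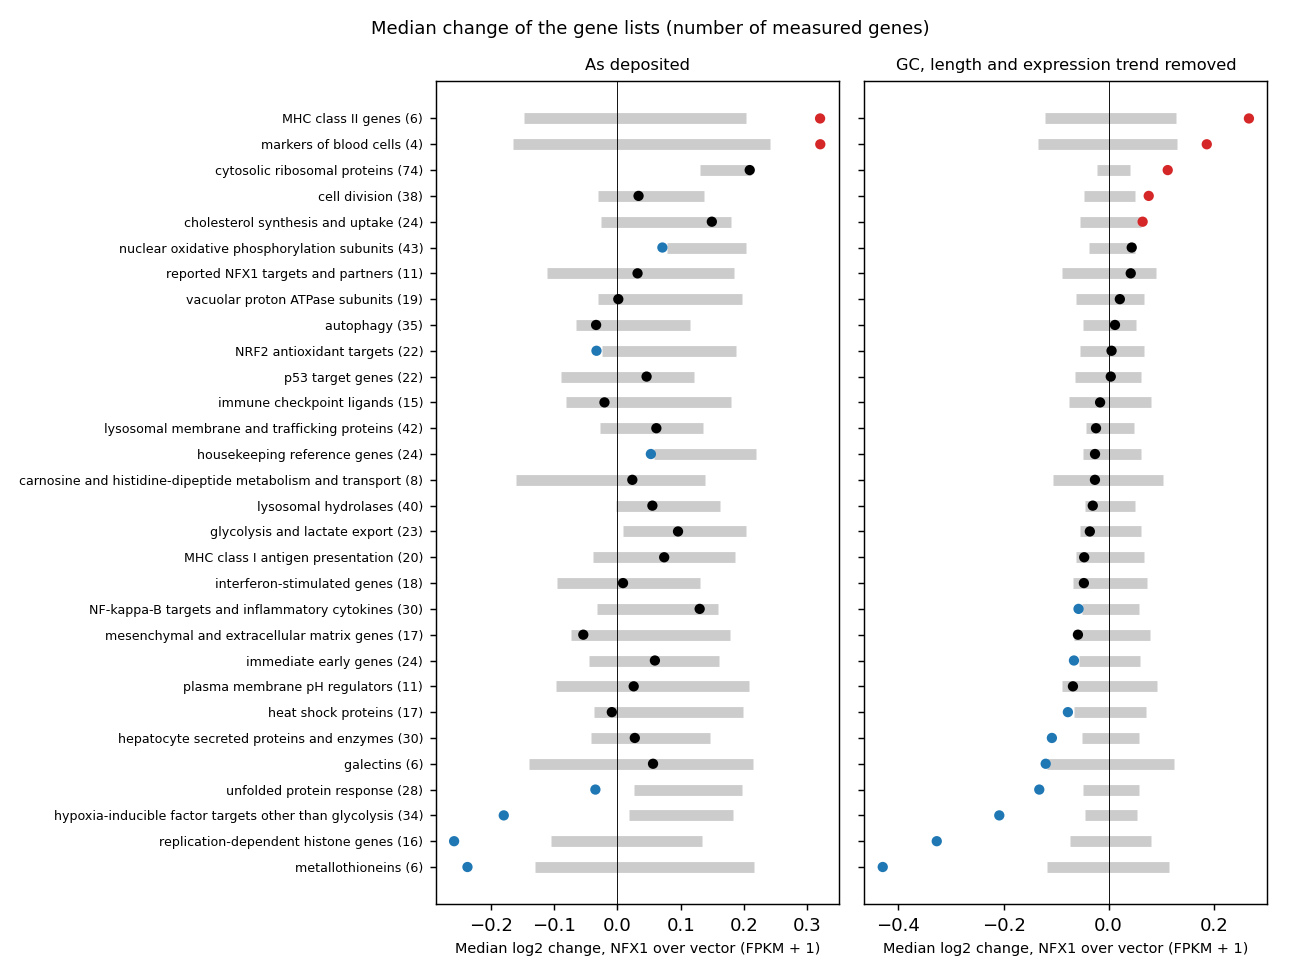
Median log2 change of each gene list as deposited (left) and after removal of the GC, length and expression trend (right), with the number of measured genes. Points are the medians, coloured red where a list stood apart on the high side and blue on the low side, and grey bars leave out 2.5% of the random lists on each side. The 34 hypoxia targets had medians of -0.18 and -0.21.

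Lists that lay below their random lists as deposited, but not once the trend was removed, were NRF2 antioxidant targets (-0.03 over 22 genes, percentile 1.62, and 48.7 afterwards), with GCLC at -0.30 (-0.19 afterwards), nuclear oxidative phosphorylation subunits (0.07 over 43 genes, percentile 1.69, and 95.9 afterwards), with NDUFS7 at 0.46 (0.18 afterwards), and housekeeping reference genes (0.05 over 24 genes, percentile 1.87, and 12.4 afterwards), with RPLP0 at 0.38 (0.21 afterwards). Markers of blood cells stood apart at a median of 0.32 over 4 genes (percentile 99.7), from HBA2 at 3.63 and 6.03 FPKM and HBA1 at 8.72 and 13.1 FPKM, while CD68 had a change of 0.10 and LYZ -0.04, which were -0.03 and 0.02 after removal of the trend. The median of the list was then 0.19, with changes of 0.43 for HBA2 and 0.35 for HBA1. The listed markers of fibroblasts and endothelial cells had FPKM under 1 in both libraries, and transcripts of the mitochondrial genome were not analysed here.

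The remaining lists lay within the random lists as deposited. Interferon-stimulated genes had a median of 0.01 over 18 genes (percentile 51.6, and 8.09 after removal of the trend), with IFITM2 at 0.38 (0.24 afterwards), and p53 targets 0.05 over 22 genes (percentile 75.4, and 56.3 afterwards), with TP53INP1 at -0.34 (-0.21 afterwards). Mesenchymal and matrix genes had -0.05 over 17 genes (percentile 5.56, and 4.30 afterwards), and were set apart on the low side with a pseudocount of 5 (percentile 2.21) and with FPKM of at least 5 (percentile 0.640). CYR61 had a change of -0.26 and TAGLN 0.44. The other 5 were set apart once the trend was removed. NF-kappa-B targets had 0.13 over 30 genes (percentile 90.7) and turned to -0.06 afterwards (percentile 1.20), with CCL2 at 1.27 and 2.41 FPKM and SOD2 at 508 and 376 FPKM. Cholesterol synthesis genes had 0.15 over 24 genes (percentile 90.3) and 0.06 afterwards (percentile 98.2), with LSS at 0.38 (0.21 afterwards). Hepatocyte genes had 0.03 over 30 genes (percentile 30.8) and turned to -0.11 afterwards (percentile 0), with APOA4 at 3.62 and 2.05 FPKM and AHSG at 13.5 and 9.70 FPKM. Immediate early genes had 0.06 over 24 genes (percentile 47.2) and turned to -0.07 afterwards (percentile 1.03) with 19 genes lower, with MCL1 at -0.28 (-0.21 afterwards) and NR4A1 at 0.35 (0.14 afterwards), and heat shock proteins -0.01 over 17 genes (percentile 6.32) and -0.08 afterwards (percentile 1.34), with CRYAB at -0.94.

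The authors' deposited table marked 18 of 14994 tested rows as significant, 13 with higher and 5 with lower values in the NFX1 library. No symbol was given for 14 of the 18 in the authors' deposited table, and 16 were listed at 0 in 1 library. NFX1 had a log2 fold change of 3.73 with p = 5e-05 and q = 0.0417 in the authors' deposited table, and all 18 shared that p and q. The only other marked row above 0 in both libraries held IGF2, INS and INS-IGF2 (3.95 and 1.81 FPKM), with a log2 fold change of -1.12 in the authors' deposited table; it was named after its values were seen, as were BREA2 (0 and 0.392 FPKM) and the cancer-testis gene CT45A4 (0 and 1.85 FPKM). These p-values come from 1 library per group and do not measure the spread between cultures.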

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

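The limits for these loci (FPKM of at least 5 in the NFX1 library and a change of at least 1) were chosen after some of the values had been seen. Outside the named genes, 17 loci without a symbol had higher values in the NFX1 library than in the vector control. Their log2 changes were 4.48, 3.29, 3.05, 3.01, 2.62, 2.46, 2.18, 2.15, 2.01, 1.85, 1.72, 1.39, 1.29, 1.17, 1.15, 1.14 and 1.08. The first lies on chromosome 11 (63937195 to 63937422, hg19), listed at 0 in the vector library and at 21.3 FPKM in the NFX1 library. A longer one on chromosome 1 (17215047 to 17216145) had 3.15 and 32.5 FPKM. Of the 17, 15 were shorter than 400 bp. Large differences went both ways: among 468 unnamed loci with FPKM of at least 1, 31 were at least 2-fold higher and 23 at least 2-fold lower, and 32 of these 54 were shorter than 400 bp.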

How the results depend on the processing

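The removal of the GC, length and expression trend, and of MT1A and MT1B from the metallothioneins, was chosen after the data had been seen; the other alternatives were fixed beforehand. No paired analysis was possible because each group has 1 library. The cause of each change below was not tested unless the setting itself shows it.

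Genes at least 2-fold higher and lower numbered 12 and 4. They were 25 and 16 with pseudocount 0.1, 1 and 0 with pseudocount 5, and 1 and 2 with FPKM of at least 5. At a 1.5-fold limit they were 47 and 24, and at a 4-fold limit 1 and 1. After removal of the trend they were 7 and 5 of 10996 genes. Some of the 12 had no GENCODE transcript and were left out of that count. The NFX1 change of 3.45 was 2.73 with pseudocount 5, 3.40 with the median ratio set to 0, 3.38 with equal sums and 3.52 after removal of the trend. The scalings moved the median of all genes from 0.01 to between -0.05 and -0.02. In the authors' deposited table, 0 rows had q of at most 0.01 and 6 of the 18 had FPKM of at least 1.

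Over 10 planned settings, 26 of 30 lists kept their side of the limits. The 3 scalings among them multiply all NFX1 values by the same factor. A list and its random lists then move almost together, so these settings test the percentiles little. Ribosomal protein genes stood apart at percentiles 97.8 (pseudocount 0.1), 98.5 (no filter), 98.3 (FPKM of at least 5), 97.7 (rows summed) and 98.1 (10 bins). Mesenchymal genes stood apart at 2.21 (pseudocount 5) and 0.640 (FPKM of at least 5). Housekeeping genes no longer did at 2.70 (no filter), 2.57 (equal sums), 8.92 (rows by status) and 2.55 (10 bins), nor MHC class II genes at 58.2 (no filter). After removal of the trend, percentiles were 2.27 for galectins, 1.20 for NF-kappa-B targets, 98.2 for cholesterol synthesis, 99.9 for cell division, 0 for hepatocyte genes, 1.03 for immediate early genes, 1.34 for heat shock proteins, 48.7 for NRF2 targets, 95.9 for oxidative phosphorylation, 100 for ribosomal proteins and 12.4 for housekeeping genes. Of 1351 values of named genes other than NFX1 and LGALS9 under the alternatives, 140 moved beyond counting error. A turn of direction was counted only for changes of at least 2-fold, here those of MT1A and MT1B, and 0 turned. Smaller changes could turn without being counted, such as that of CD68, from 0.10 to -0.03 after removal of the trend.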

Other observations

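The tests on glycolytic genes and on cell division genes were chosen, and their bounds rewritten, after the results were seen, as was the metallothionein list without 2 members; the GC, length and expression adjustment was chosen after the list medians were seen, and its bounds were written before its own result.

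The genes of the CT45A cancer-testis family, chosen after their values were seen, summed to 3.30 FPKM in the vector library and 8.10 FPKM in the NFX1 library. CT45A10 had 3.05 and 4.29 FPKM and CT45A7 0.250 and 1.96 FPKM. Metallothionein 1 genes together summed to 7653 and 6311 FPKM, nearly all of it from MT1X.

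Lower targets of hypoxia-inducible factors. The GC, length and expression trend as fitted does not account for the whole of this pattern, since the list stayed at percentile 0 after adjustment. A weaker response to low oxygen in the whole NFX1 culture remains open: glycolytic genes, taken here to answer to the same factor, lay at percentile 9.13 after adjustment, neither clearly lower nor on the opposite side. Their median lay above that of the hypoxia targets by 0.27 (bootstrap SD 0.05) as deposited and 0.17 (bootstrap SD 0.05) after adjustment. That SD covers the spread over genes and not between cultures, and the hypoxia targets were taken up because their list stood apart. The gap therefore does not decide the question. Without a normoxic library the response of each gene in this line is also unknown. An effect of NFX1 and a difference between 2 single cultures cannot be told apart here.

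Lower replication-dependent histone genes. This list also stayed at percentile 0 after adjustment, which argues against the trend as fitted being the whole cause. Fewer dividing cells would lower cell division genes, which lay at percentile 32.8 as deposited and 99.9 after adjustment. Their median lay above that of the histone genes by 0.29 (bootstrap SD 0.07) as deposited and 0.40 (bootstrap SD 0.10) after adjustment. The SD again covers only the spread over genes, and the histone genes were taken up because their list stood apart. The gap therefore does not decide the question. Fewer dividing cells stay open, since the deposited percentile lies within the random lists. Fewer cells in S phase also remain open, because the list mixes genes of S phase and of mitosis and cannot speak for S phase alone. Carry-over of RNA without a poly(A) tail also remains open, because 9 other such RNAs had a median change of 0.17 (bootstrap SD 0.20), from SCARNA12 at 0.85 to SNORD116-4 at -0.39. An effect of NFX1 was not tested apart from the difference between single cultures.

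Other lists that stood apart as deposited. After adjustment the percentiles of NRF2 targets (48.7), oxidative phosphorylation subunits (95.9) and housekeeping genes (12.4) were within the random lists, so the trend may account for those 3; their medians were -0.03, 0.07 and 0.05 before and 0.01, 0.04 and -0.03 after. The unfolded protein response and metallothioneins went from percentiles 0.090 and 0.050 to 0 after adjustment. MHC class II genes lay at 99.99 and blood cell markers at 99.65 after it. The trend as fitted leaves these lists unexplained. Metallothioneins, MHC class II genes and blood cell markers have 6, 6 and 4 measured genes, and without the uncertain MT1A and MT1B the metallothionein median went from -0.24 to -0.12 (percentile 2.27), and to -0.30 after adjustment (percentile 0.070). The same adjustment set 8 further lists apart, so list results here depend on how base composition is treated.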
